A study of Mus musculus with 12 samples.

How the data were processed

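Nuclear RNA of microglia from mouse spinal cord was sequenced in 12 libraries, 3 from sham-operated mice and 3 each at 3, 7 and 14 days after injury, per the labels. Per the labels' protocols, each library pooled cord tissue of 3 C57BL/6 mice, nuclei were isolated on an iodixanol gradient and GFP-positive nuclei were captured with an antibody and magnetic beads. The RNA was amplified by a single-primer isothermal method before libraries were made. Per the submitters' processing notes, featureCounts 1.4.6-p3 and the builds GRCm38 and mm10 were used; the aligner, the strand setting and the handling of reads with several matches are not given in the sources used here. The authors deposited a table of raw counts per Ensembl gene (unit: count) and a table of RPKM, which are scaled by gene length and library total. The deposited RPKM equal the count divided by a gene length and by the library total, with a largest relative difference of 6.4e-15.

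The count table holds 49585 genes, of which 15460 have no count in any library. The 37 rows of the mitochondrial genome hold 0 counts, so mitochondrial transcripts were not assessed. All 12 columns were mapped to their group and replicate. Total counts ranged from 4003480 to 10670804. Pearson correlations of log2 CPM between libraries of a group were 0.880 to 0.979, and the spread between libraries was larger than counting error (chi-square per degree of freedom of 4.76 or more). A symbol was shared by more than 1 ID in 93 cases (186 IDs), and IDs were kept apart.

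Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (18451 genes, 99.6% of counts) were scaled by TMM and fitted with a quasi-likelihood model of the 4 groups over all 12 libraries, with a common biological coefficient of variation of 0.271. The 6 pairwise comparisons and a test of any difference were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. The SE is the log2 fold change divided by the square root of the F statistic. Before the data were examined, 36 gene lists were fixed, 14 of them for other cell types. The 34 lists with at least 3 measured genes were tested with fry of limma 3.58.1, which asks whether the genes of a list move, on balance, one way and does not compare them with other genes. To compare 3 lists with 5 others from 7 to 14 days, fry was run once with gene weights of opposite sign, which tests the mean change of the 3 minus that of the 5 against the spread between libraries. Components were computed on log2 CPM with a prior count of 2. Sums of a list over 3 against 3 libraries were compared by an exact two-sided permutation test, whose smallest p is 0.10. Gene positions were read from the GENCODE annotation of GRCm38. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

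Named genes follow a rule. Plxnb2 is given in every comparison. Against sham these are the 8 largest rises and the 8 largest falls past the threshold (5 and 5 between times) in which the 3 libraries of each group do not overlap and the mean is at least 10 CPM, with predicted genes and pseudogenes passed over. From each list up to 4 members past the threshold with the smallest adjusted p are eligible, or else up to 2 with the highest mean CPM as values. Some genes that meet the rule are not reported here.

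The alternatives were median-ratio size factors, DESeq2 1.42.0, no filter on low counts, a stricter filter (at least 1 CPM in 3 libraries and a mean of at least 5 CPM), the replicate number as a term, a fit of only the 2 groups compared, limma on log2 RPKM with a pseudocount of 1 or 0.1, each library left out in turn, and camera with an estimated correlation in place of fry. Camera compares the genes of a list with the other genes, which fry does not, and estimates the correlation between the genes of the list. The summed CPM of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty as a covariate was added after their levels were seen. On simulated data of 18451 genes with 200 changed at 3 days, 14% of 2-fold and 63% of 4-fold changes were recovered. There were 3 false calls among 80 and 0 calls in the unchanged comparisons. In the real 3-day comparison 3695 genes were called. With fewer changed genes the Benjamini-Hochberg threshold is stricter, so the simulated recovery does not measure that of the real comparisons.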

Results

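RNA of nuclei captured as microglial was measured after spinal cord injury in 12 libraries from C57BL/6 mice. There were 3 libraries each from sham-operated mice and from injured mice at 3, 7 and 14 days, and the sham libraries carry the 7-day label. Each library pools cord tissue of 3 animals around the lesion. Nuclei carrying green fluorescent protein (GFP) were pulled down with an antibody against it, so nuclear RNA was sequenced and cytoplasmic RNA was largely left behind. Total counts were 7064757, 4069787 and 4003480 in sham replicates 2, 3 and 4, and 4344015, 6610377 and 10670804 in 3-day replicates 1, 2 and 3. They were 5047851, 6026349 and 7232561 in 7-day replicates 1, 3 and 4, and 6313722, 4037508 and 4272439 in 14-day replicates 1, 2 and 3. Of 49585 annotated genes, 18451 had enough counts for a test. Levels are in CPM (counts scaled to a common library total) as mean ± SD with n = 3 libraries, and log2 fold changes are given ± SE. CPM are scaled by TMM, except for sums over several genes and for Xist, Gm26917 and Rn18s-rs5. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes, and those of gene lists from limma's fry test, adjusted over the 34 lists tested. These p-values measure the spread between libraries, each of which already averages 3 animals.

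Genes differed widely between the 4 groups: 4872 of 18451 genes changed in a test of any difference (edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment). The count was 2926 without 3-day replicate 3 and 3239 without 14-day replicate 1. Component 1 of log2 CPM (26.7% of the variance) placed the 3-day libraries at -72.6 to -47.5 and the 14-day libraries at -22.9 to -17.3. The 7-day libraries lay at 14.2 to 55.9, and the sham libraries at 7.55 to 70.3. Component 2 (23.5%) held sham replicate 4 apart at 119.8, with the next library at 26.8. Markers of other cell types were also high in that library: its summed astrocyte markers were 5474 CPM against 762.5 and 1964 in sham replicates 2 and 3, and its fibroblast and pericyte markers 502.1 against 74.0 and 101 CPM. Sex-linked genes differed between the pools of a group. Xist, transcribed from the inactive X of females, was below 5 CPM in 2 of the 3 libraries at 7 days, replicates 3 and 4, and in 14-day replicate 3 (4.81, 0.968 and 0.936 CPM). These Xist values are not scaled by TMM. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 0.708, 0.460 and 0.375 CPM in sham replicate 2 and in 2 of the 3 libraries at 3 days, replicates 1 and 3.

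**Figure D1:**
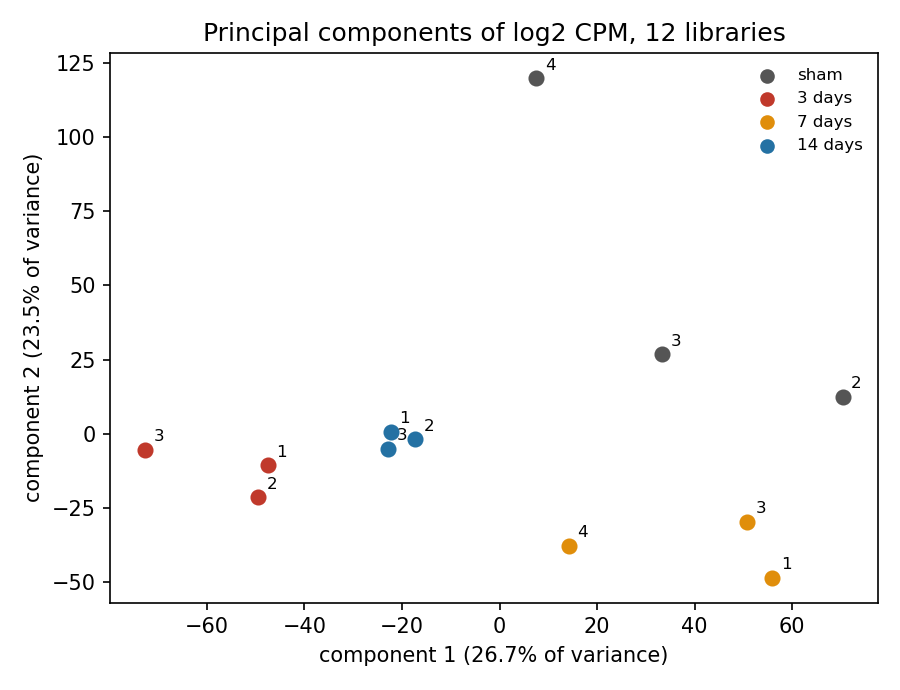
Each point is 1 of the 12 libraries, placed by component 1 (26.7% of variance, x axis) and component 2 (23.5%, y axis) of log2 CPM, coloured by group and numbered by replicate. Sham replicate 4 lies at 119.8 on component 2, and the next library at 26.8.

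The series concerns Plexin-B2, and the first question is when its gene was higher. Plxnb2 (ENSMUSG00000036606; GRCm38 chromosome 15, 89155549 to 89180788, minus strand, 8 annotated transcripts) encodes a receptor for class 4 semaphorins. Its level was 306.9 ± 42.9 CPM in sham, 467.8 ± 10.4 at 3 days, 354.0 ± 68.2 at 7 days and 289.8 ± 13.8 at 14 days. It rose at 3 days, with a log2 fold change of 0.61 ± 0.16 (edgeR adjusted p = 0.018) and all 3 injured libraries above the 3 sham libraries. At 7 days the log2 fold change against sham was 0.21 ± 0.16 (edgeR adjusted p = 0.445) and at 14 days -0.08 ± 0.16 (edgeR adjusted p = 0.792). The value at 7 days was 0.09 without sham replicate 4, and 0.13, 0.35 and 0.09 without 7-day replicates 1, 3 and 4. The value at 14 days turned positive without sham replicate 3 (0.01) and on RPKM (0.05 with either pseudocount). From 3 to 14 days Plxnb2 fell by 0.69 on the log2 scale (edgeR adjusted p = 0.0193). From 3 to 7 days the log2 fold change was -0.40 ± 0.16 (edgeR adjusted p = 0.111), and -0.23 without 7-day replicate 3. From 7 to 14 days it was -0.29 ± 0.16 (edgeR adjusted p = 0.378), and -0.45 and -0.17 without 7-day replicates 3 and 4. The call at 3 days ended on leaving out 3-day replicate 1 (0.59, edgeR adjusted p = 0.0514), replicate 2 (0.57, 0.0708) or replicate 3 (0.59, 0.0645), and when the fit held those 6 libraries alone (0.58, 0.0646). The fall from 3 to 14 days ended without 3-day replicate 1, 2 or 3 (edgeR adjusted p = 0.0639, 0.0785 and 0.0784) or 14-day replicate 1, 2 or 3 (0.124, 0.0927 and 0.0918).

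**Figure D2:**
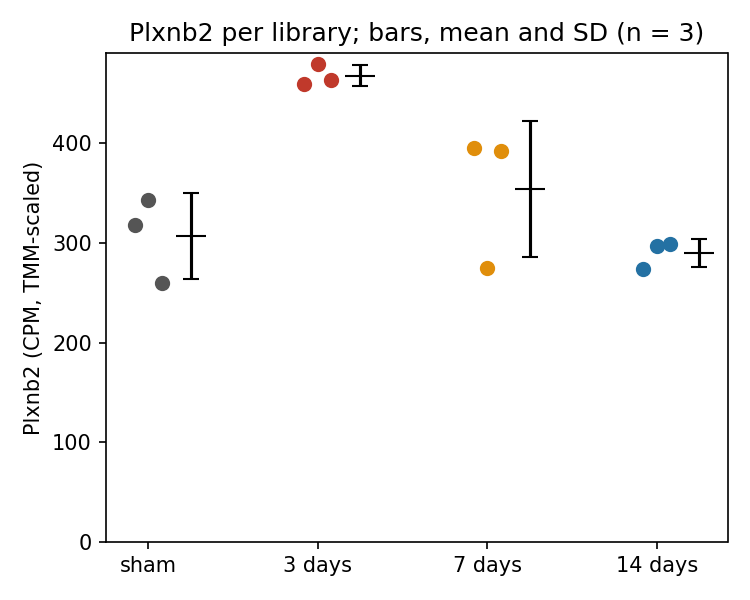
Plxnb2 in each of the 12 libraries (points, CPM scaled by TMM on the y axis, groups on the x axis), with the mean and SD of the 3 libraries of each group as bars. The 3-day libraries lie at 459.9 to 479.5 CPM, above the sham libraries at 259.5 to 343.1 CPM.

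At 3 days, 16 of 24 genes of the damage-associated microglial state, all 24 mitosis genes, all 23 interferon-stimulated genes and 17 of 24 matrix genes rose in the captured nuclei. Of 24 homeostatic microglial genes 11 fell, a list with adjusted p = 0.155 with an estimated correlation. Summed markers of monocyte-derived macrophages, Fn1 among them, were 6.68 times sham at the same time. Those of endothelial cells were 311.9 to 760.2 CPM against 54.9, 56.0 and 199.6 in sham replicates 2, 3 and 4. Gpnmb (ENSMUSG00000029816; chromosome 6, 49036546 to 49070929, plus strand), a membrane glycoprotein of phagocytes, went from 1.87 ± 0.468 CPM in sham to 320.2 ± 56.9, a log2 fold change of 7.45 ± 0.42 (edgeR adjusted p = 8.65e-08). Spp1 (ENSMUSG00000029304; chromosome 5, 104435118 to 104441050, plus strand), which encodes osteopontin, rose from 10.7 ± 4.39 to 585.3 ± 139 CPM, by 5.81 ± 0.44 on the log2 scale. The other large rises were Ch25h, the cholesterol 25-hydroxylase (5.72 ± 0.41), the matrix genes Thbs1 (5.55 ± 0.40) and Fn1 (4.91 ± 0.53), the Schlafen gene Slfn4 (5.21 ± 0.62), Stra6l (5.02 ± 0.35) and the metalloprotease gene Adam8 (4.76 ± 0.39). The largest falls were Upk1b (-2.89 ± 0.46), Lyve1, a hyaluronan receptor of macrophages at tissue borders (-2.83 ± 0.54), Sh3gl2 (-2.73 ± 0.41), Ighd (-2.41 ± 0.38), Tlr5, the flagellin receptor (-2.38 ± 0.36), Gpr165 (-2.37 ± 0.30), the synapse gene Syn1 (-2.33 ± 0.53, from 134.6 ± 145 to 26.7 ± 1.64 CPM) and Bank1 (-2.24 ± 0.29). These 16 genes were picked among called genes whose 3 injured libraries lay wholly above or below the 3 sham libraries. That separation therefore adds no evidence. Their highest edgeR adjusted p was 0.00714.

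Of 24 damage-associated genes, 16 rose, 0 fell and 8 did not pass at 3 days (18 rose when adjusted over the list alone), and the list moved up (fry adjusted p = 9.65e-06, median log2 fold change 1.48). Besides Gpnmb and Spp1 it held Csf1, the growth factor of macrophages (3.16 ± 0.31), and Lilrb4a, an inhibitory receptor (2.26 ± 0.24). Of 24 homeostatic genes 11 fell and 0 rose (12 fell when adjusted over the list alone; fry adjusted p = 0.00382, and adjusted p = 0.155 with an estimated correlation). The purinergic receptor gene P2ry12, which guides microglial processes, fell by 2.13 ± 0.34 and P2ry13 by 2.07 ± 0.32, with Maf (-1.38 ± 0.21) and Siglech (-1.20 ± 0.19). Of 22 genes of lipid uptake and efflux 12 rose and 1 fell (13 and 1 when adjusted over the list alone; fry adjusted p = 9.65e-06). Examples were the cholesterol exporters Abca1 (1.61 ± 0.17) and Abcg1 (1.71 ± 0.24) and the scavenger receptor Msr1 (2.35 ± 0.28). Of 24 phagocytosis and lysosome genes 9 rose and 1 fell (11 and 1 when adjusted over the list alone; fry adjusted p = 0.000954, and adjusted p = 0.149 with an estimated correlation). Examples were Axl, a receptor for dying cells (2.05 ± 0.29), and the protease gene Ctsb (1.53 ± 0.22). Lists share genes: 14 of the 24 damage-associated genes are also in another list.

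All 24 mitosis genes rose at 3 days, by a median of 3.19 on the log2 scale (fry adjusted p = 9.65e-06), and their summed level was 2777 ± 210 CPM against 383.6 ± 150 in sham. Cenpe, a kinetochore motor, had a log2 fold change of 3.58 ± 0.20 (edgeR adjusted p = 8.65e-08). Of 24 DNA replication genes 19 rose and 0 fell (21 when adjusted over the list alone; fry adjusted p = 8.3e-06). Examples were the helicase component Cdc45 (2.15 ± 0.29), the ribonucleotide reductase subunit Rrm2 (3.94 ± 0.43) and Mcm10 (3.96 ± 0.52). All 23 interferon-stimulated genes rose (fry adjusted p = 3.17e-06, median 2.21). Examples were Rsad2 (4.43 ± 0.38), Ifit2 (3.61 ± 0.28) and the transcription factor gene Irf7 (2.71 ± 0.25). The counts for mitosis and interferon were the same when adjusted over the list alone. Of 18 measured inflammatory genes 9 rose and 2 fell (10 and 2 when adjusted over the list alone; fry adjusted p = 9.65e-06). Ccl3 (2.45 ± 0.23) and Tnf (2.87 ± 0.33) rose, and Il6, encoding interleukin 6, fell by 4.08 ± 0.44, from 12.6 ± 2.89 to 0.774 ± 0.316 CPM. Of 24 matrix and wound genes 17 rose and 0 fell (19 when adjusted over the list alone; fry adjusted p = 9.65e-06).

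Of the 11 plexins and neuropilins, 6 rose, 1 fell and 4 did not pass at 3 days (8 and 1 when adjusted over the list alone; fry adjusted p = 0.000636, and adjusted p = 0.106 with an estimated correlation). Plxna1 (1.79 ± 0.34), Plxnc1 (1.37 ± 0.22) and Nrp1, a co-receptor for semaphorins and VEGF (0.96 ± 0.15), rose with Plxnb2, and Plxna4 fell by 1.10 ± 0.20. Of the 20 semaphorins 4 rose and 0 fell (5 and 1 when adjusted over the list alone; fry adjusted p = 0.113), with Sema7a at 2.17 ± 0.38. Of 24 cytoskeleton and motility genes 10 rose and 1 fell, the same counts as when adjusted over the list alone (fry adjusted p = 1.08e-05), led by the scaffold gene Iqgap1 (2.58 ± 0.20) and the actin linker Tln1 (1.30 ± 0.18). Of 19 measured genes of oxidative stress and iron 6 rose and 1 fell (7 and 1 when adjusted over the list alone; fry adjusted p = 9.65e-06, and adjusted p = 0.0568 with an estimated correlation). The haem oxygenase gene Hmox1 was the largest of these (4.72 ± 0.36, from 8.22 ± 4.91 to 226.8 ± 46.3 CPM). Of 20 glycolysis and hypoxia genes 12 rose and 0 fell (13 when adjusted over the list alone; fry adjusted p = 0.000252, and adjusted p = 0.105 with an estimated correlation). Examples were Pfkl (1.96 ± 0.24), Ldha (1.60 ± 0.22) and Pkm (1.36 ± 0.17).

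Smaller sets moved as well at 3 days. Of 19 antigen presentation genes 6 rose and 1 fell (fry adjusted p = 9.84e-06, and adjusted p = 0.0507 with an estimated correlation). Examples were Nlrc5, the activator of class I genes (2.38 ± 0.23), and Cd74 (1.74 ± 0.31). Of 17 complement genes 6 rose and 1 fell (8 and 1 when adjusted over the list alone; fry adjusted p = 0.000277, and adjusted p = 0.0568 with an estimated correlation). Of 15 measured growth factor genes 3 rose (5 when adjusted over the list alone), Csf1, Vegfa (1.35 ± 0.21) and Igf1 (1.80 ± 0.39), with fry adjusted p = 0.00022 and adjusted p = 0.0682 with an estimated correlation. Of 15 immediate early and heat shock genes, which also respond to tissue handling, 9 rose and 1 fell (11 and 1 when adjusted over the list alone; fry adjusted p = 5.91e-05), including Atf3 (2.64 ± 0.23). Of 15 alternative activation genes 4 rose and 4 fell, with Arg1 up (3.53 ± 0.43) and Mgl2 down (-2.74 ± 0.47). That list's call (fry adjusted p = 0.0406, and adjusted p = 0.781 with an estimated correlation) ended under 13 of 16 alternatives, with p up to 0.152 when 1 library was left out.

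Markers of other cells moved with injury at 3 days too. All 14 endothelial markers rose (the same when adjusted over the list alone; fry adjusted p = 0.00119, and adjusted p = 0.125 with an estimated correlation), and their sum was 473.8 ± 249 CPM against 103.5 ± 83.2 in sham. Kdr, the VEGF receptor, went up by 2.66 ± 0.26. Fibroblast and pericyte markers summed to 535.3 ± 334 CPM against 225.6 ± 240 in sham, with 3 of 14 genes higher and fry adjusted p = 0.232. Of 16 measured markers of monocyte-derived macrophages, cells that enter from blood, 10 rose and 0 fell, also when adjusted over the list alone (fry adjusted p = 0.000444, and adjusted p = 0.0815 with an estimated correlation). Their sum was 2398 ± 172 CPM against 359.0 ± 164, with Fn1 and Lyz2 (2.66 ± 0.25) among them. Although Lyve1 fell, markers of border-associated macrophages summed to 1236 ± 129 CPM against 1107 ± 151 in sham. Of 17 neuron markers 12 fell and 0 rose (13 when adjusted over the list alone; fry adjusted p = 0.000121), from a sum of 2402 ± 758 to 967.2 ± 69.0 CPM. The exact two-sided permutation test of 3 against 3 libraries cannot go below p = 0.10, which it gave for the sums of the endothelial, monocyte and neuron lists. Cspg4, which encodes the NG2 proteoglycan, rose by 4.39 ± 0.33 while 10 of the 12 precursor markers it is listed with did not pass.

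In all, 3695 of 18451 genes changed at 3 days against sham, 2003 up and 1692 down (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 21 of 34 lists did so by fry. The count was 2060 without 3-day replicate 2, 1866 without replicate 3, and 1817 when the fit held those 6 libraries alone. By camera 10 lists passed with an estimated correlation.

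**Figure D3:**
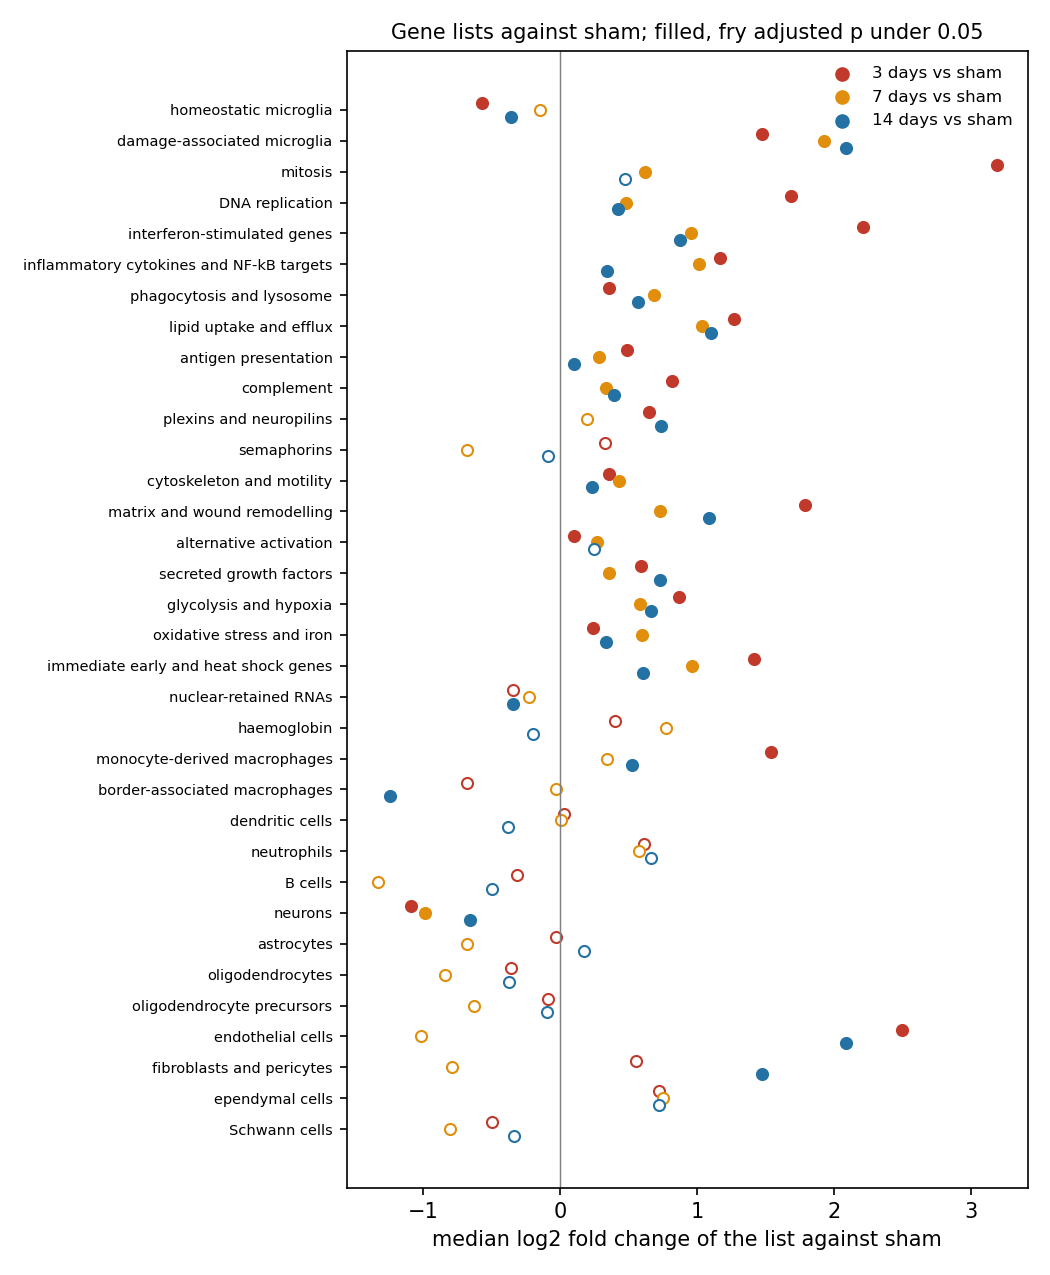
Median log2 fold change against sham (x axis) of the 34 gene lists tested (y axis) at 3, 7 and 14 days, with filled points where the fry adjusted p was under 0.05. The mitosis list lies at 3.19 at 3 days and at 0.62 and 0.48 at 7 and 14 days, while the damage-associated list lies at 1.48, 1.93 and 2.09.

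At 7 days the damage-associated and lipid genes were high. The homeostatic list did not differ detectably from sham by fry, though its sum was lower in all 3 libraries. Gpnmb stood at 460.6 ± 205 CPM (log2 fold change 7.97 ± 0.42, edgeR adjusted p = 1.15e-07). Stra6l (5.51 ± 0.35), Ch25h (4.50 ± 0.41), Spp1 (4.09 ± 0.41), the cation channel gene Trpc4 (3.76 ± 0.54), Cspg4 (3.56 ± 0.32), the chemokine gene Cxcl10 (3.44 ± 0.40) and the secreted kinase gene Fam20c (3.38 ± 0.38) followed. All were picked by the rule that the 3 injured libraries lie above the 3 sham libraries. Among the largest falls were Atp13a4 (-2.55 ± 0.53), Rorb (-2.47 ± 0.54) and Car10 (-2.43 ± 0.53), with edgeR adjusted p of 0.00952 to 0.0127. The calls for Rorb and Car10 ended when the fit held the 6 libraries alone (edgeR adjusted p = 0.0775 and 0.077), and that for Rorb without 7-day replicate 1 (0.0577).

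Of 24 damage-associated genes 17 rose and 0 fell at 7 days (19 when adjusted over the list alone; fry adjusted p = 2.21e-05, median 1.93). Examples were Lpl, the lipoprotein lipase (3.03 ± 0.29), and the integrin gene Itgax (2.42 ± 0.25). Of 22 lipid genes 11 rose and 0 fell (13 when adjusted over the list alone; fry adjusted p = 4.85e-05). Examples were Abca1 (1.87 ± 0.17) and Abcg1 (2.31 ± 0.24). Of 24 homeostatic genes 0 rose and 0 fell, also when adjusted over the list alone (fry adjusted p = 0.357). Their sum was 10010, 9442 and 8239 CPM at 7 days against 11700, 10550 and 10570 in sham (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Csf1r was at 1325 ± 116 CPM against 1181 ± 270 in sham. Of 23 interferon-stimulated genes 17 rose and 0 fell (18 when adjusted over the list alone; fry adjusted p = 5.16e-05). Examples were Irf7 (2.21 ± 0.25) and Ifit3 (2.37 ± 0.31). Of 18 inflammatory genes 8 rose and 1 fell (11 and 1 when adjusted over the list alone; fry adjusted p = 5.16e-05), with Ccl3 up (2.00 ± 0.23) and Il6 down (-2.28 ± 0.39). Of 24 phagocytosis and lysosome genes 10 rose (15 when adjusted over the list alone; fry adjusted p = 0.000323, and adjusted p = 0.0617 with an estimated correlation). Examples were Axl (1.73 ± 0.29) and the protease gene Ctsd (1.29 ± 0.23). Immediate early and heat shock genes, which also respond to tissue handling, summed to 531.9 ± 67.7 CPM against 369.0 ± 70.9 in sham. Growth factor genes rose in 4 of 15 cases, also when adjusted over the list alone: Igf1 (2.66 ± 0.40), Csf1 (2.28 ± 0.30), Pdgfa (1.54 ± 0.24) and Hgf (1.13 ± 0.29), with fry adjusted p = 0.00221 and adjusted p = 0.144 with an estimated correlation. Of 24 cytoskeleton genes 5 rose and 0 fell (7 when adjusted over the list alone; fry adjusted p = 5.16e-05).

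All 24 mitosis genes were lower at 7 days than at 3 days in the direct comparison (adjusted p = 0.112 for the list with an estimated correlation). Against sham 4 of 24 were higher (8 when adjusted over the list alone; fry adjusted p = 0.0488, and adjusted p = 0.338 with an estimated correlation). That call ended under 13 of 16 alternatives, with p up to 0.199 without sham replicate 3. Of 24 DNA replication genes 4 rose (7 when adjusted over the list alone; fry adjusted p = 0.00277, and adjusted p = 0.119 with an estimated correlation). Of 24 matrix genes 9 rose and 1 fell (11 and 1 when adjusted over the list alone; fry adjusted p = 0.000556, and adjusted p = 0.0911 with an estimated correlation). Examples were the urokinase gene Plau (1.68 ± 0.20) and Lgals3 (3.11 ± 0.41). Of the 11 plexins and neuropilins 3 rose, Nrp1 (0.88 ± 0.15), Plxnc1 (0.94 ± 0.22) and Nrp2 (0.75 ± 0.18), also when adjusted over the list alone, where 2 more fell (fry adjusted p = 0.281). Of 20 semaphorins 1 rose and 4 fell (2 and 4 when adjusted over the list alone; fry adjusted p = 0.132). Markers of the vessel wall were not raised at 7 days: the endothelial sum was 67.2 ± 13.9 CPM and the fibroblast and pericyte sum 107.2 ± 55.1. Of 17 neuron markers 8 fell (10 when adjusted over the list alone; fry adjusted p = 0.000337). Map2, which encodes a dendrite protein, was among them (-1.29 ± 0.20). Monocyte-derived macrophage markers summed to 728.3 ± 291 CPM, with 2 of 16 genes higher, also when adjusted over the list alone, and fry adjusted p = 0.118.

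At 7 days 1712 genes changed against sham, 851 up and 861 down (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 17 of 34 lists by fry, of which 6 passed with an estimated correlation. The count was 3065 without sham replicate 2, 827 without 7-day replicate 1, 947 without 7-day replicate 4, 2889 with no filter on low counts and 172 when the fit held those 6 libraries alone. With limma on RPKM, which is scaled by library totals, the split was 663 up to 474 down with a pseudocount of 1 and 651 to 418 with 0.1.

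At 14 days damage-associated, lipid and matrix genes were above sham. Below it were 7 of 24 homeostatic and 6 of 10 border macrophage genes (adjusted p = 0.303 and 0.288 with an estimated correlation). Gpnmb was at 400.1 ± 81.7 CPM (log2 fold change 7.77 ± 0.42, edgeR adjusted p = 1.57e-07). Stra6l (5.98 ± 0.35), Trpc4 (4.94 ± 0.54), Ch25h (4.54 ± 0.42), Spp1 (4.34 ± 0.41), Cspg4 (4.32 ± 0.33), Fam20c (4.24 ± 0.38) and the chemokine receptor gene Cxcr4 (3.99 ± 0.37) completed the 8 largest rises. The rule picks such genes only where injured and sham libraries do not overlap. Among the largest falls were Mirg (-3.94 ± 0.80), Snhg11 (-3.70 ± 0.44), Meg3 (-3.31 ± 0.46, from 1561 ± 1197 to 158.1 ± 56.7 CPM), Mir124a-1hg, the host of a neuronal microRNA (-3.06 ± 0.46), the ryanodine receptor gene Ryr3 (-2.88 ± 0.38) and Arpp21 (-2.88 ± 0.31). Of 17 neuron markers 3 fell and 14 did not pass (8 fell when adjusted over the list alone; fry adjusted p = 0.0037, and adjusted p = 0.117 with an estimated correlation), and their sum was 1688 ± 327 CPM against 2402 ± 758 in sham. Sham replicate 4 was at 3243 CPM and replicates 2 and 3 at 1772 and 2191 (exact two-sided permutation p = 0.2). Of 10 nuclear-retained RNAs 3 fell, also when adjusted over the list alone, with Miat beside Snhg11 and Meg3 (fry adjusted p = 0.013, and adjusted p = 0.227 with an estimated correlation). The call for nuclear-retained RNAs ended without 14-day replicate 3 (fry adjusted p = 0.0554). Xist is also in that list, at 0.936 CPM in this replicate against 15990 and 8127 in 14-day replicates 1 and 2. The list summed to 39570 ± 8666 CPM at 14 days against 39710 ± 13030 in sham (exact two-sided permutation p = 0.9). The 3 falls therefore do not show a lower level of these RNAs as a whole.

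Of 24 damage-associated genes 18 rose and 0 fell at 14 days (19 when adjusted over the list alone; fry adjusted p = 8.05e-06, median 2.09). Examples were Itgax (3.29 ± 0.26), Lpl (3.70 ± 0.29) and Apoe, the main lipid carrier of the nervous system (3.31 ± 0.30, from 40.6 ± 2.78 to 401.5 ± 160 CPM). Of 22 lipid genes 11 rose and 1 fell (12 and 1 when adjusted over the list alone; fry adjusted p = 2.56e-05). Of 24 phagocytosis and lysosome genes 11 rose (13 when adjusted over the list alone; fry adjusted p = 0.000529, and adjusted p = 0.0919 with an estimated correlation). Examples were Ctsb (1.91 ± 0.22), Axl (2.27 ± 0.30) and Ctss (1.22 ± 0.23). Growth factor genes rose in 4 of 15 cases (6 when adjusted over the list alone; fry adjusted p = 0.000139), with Igf1 at 230.9 ± 14.5 against 30.6 ± 25.9 CPM. Of 24 matrix genes 13 rose (15, with 1 lower, when adjusted over the list alone; fry adjusted p = 0.00012). Examples were Plau (2.38 ± 0.21), its receptor Plaur (2.87 ± 0.31) and Fn1 (3.62 ± 0.50). Of 24 homeostatic genes 7 fell (10, with 1 higher, when adjusted over the list alone; fry adjusted p = 0.0357, and adjusted p = 0.303 with an estimated correlation). Examples were Siglech (-1.07 ± 0.19) and Maf (-1.09 ± 0.21). The call ended without sham replicate 2 (fry adjusted p = 0.117), sham replicate 4 (0.0616), 14-day replicate 1 (0.101) or 14-day replicate 3 (0.124).

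Interferon-stimulated genes were above sham in 11 of 23 cases at 14 days (13 when adjusted over the list alone; fry adjusted p = 0.000534, and adjusted p = 0.0919 with an estimated correlation), with Ifit2 at 1.62 ± 0.27. Of 18 inflammatory genes 7 rose and 1 fell (7 and 2 when adjusted over the list alone; fry adjusted p = 0.000534, and adjusted p = 0.136 with an estimated correlation). Examples were Ccl3 (2.55 ± 0.23) and Ccl4 (1.91 ± 0.37). The immediate early and heat shock genes, which also respond to tissue handling, summed to 597.8 ± 74.0 CPM against 369.0 ± 70.9 in sham. Of 24 mitosis genes 2 rose and 1 fell (3 and 1 when adjusted over the list alone; fry adjusted p = 0.0966). Of the 11 plexins and neuropilins 3 rose and 2 fell (4 and 2 when adjusted over the list alone). Plxnc1 (1.47 ± 0.22), Nrp1 (1.10 ± 0.15) and Nrp2 (0.85 ± 0.18) rose and Plxnb3 fell (-1.42 ± 0.25). That list's call (fry adjusted p = 0.0251, and adjusted p = 0.327 with an estimated correlation) ended without sham replicate 2 (0.117), sham replicate 4 (0.0646), 14-day replicate 1 (0.0684) or 14-day replicate 3 (0.077). Of 20 semaphorins 4 rose and 1 fell (5 and 3 when adjusted over the list alone; fry adjusted p = 0.356), and this list's median of -0.09 and mean of 0.23 differ in sign. Of 20 glycolysis and hypoxia genes 10 rose and 1 fell (11 and 2 when adjusted over the list alone; fry adjusted p = 0.0016, and adjusted p = 0.136 with an estimated correlation), with Gapdh at 1.43 ± 0.26. Of 24 cytoskeleton genes 7 rose (9 when adjusted over the list alone; fry adjusted p = 0.000341, and adjusted p = 0.0919 with an estimated correlation). Examples were Myo1e (2.18 ± 0.27) and the actin-severing factor gene Cfl1 (1.24 ± 0.20).

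Of 14 endothelial markers 8 rose at 14 days (13 when adjusted over the list alone; fry adjusted p = 0.00461, and adjusted p = 0.144 with an estimated correlation), and their sum was 514.1 ± 2.57 CPM against 103.5 ± 83.2 in sham, with Flt1 at 3.11 ± 0.57. Fibroblast and pericyte markers summed to 743.1 ± 64.5 against 225.6 ± 240 CPM, with 2 of 14 higher (5 when adjusted over the list alone; fry adjusted p = 0.0176, and adjusted p = 0.227 with an estimated correlation), Postn (2.94 ± 0.32) and Vtn (3.21 ± 0.52). The fibroblast call ended without sham replicate 2 (fry adjusted p = 0.0746), sham replicate 3 (0.0578) or 14-day replicate 1 (0.0541). Monocyte-derived macrophage markers summed to 1482 ± 81.8 against 359.0 ± 164 CPM, with 5 of 16 higher (6 when adjusted over the list alone; fry adjusted p = 0.013, and adjusted p = 0.227 with an estimated correlation). That call ended without sham replicate 2 (fry adjusted p = 0.0514) or sham replicate 3 (0.0502). Markers of border-associated macrophages went the other way: 6 of 10 fell (6 and 1 higher when adjusted over the list alone) and the sum went from 1107 ± 151 to 632.7 ± 92.3 CPM. Stab1, a scavenger receptor, fell by 0.95 ± 0.14. That list's call (fry adjusted p = 0.0357, and adjusted p = 0.288 with an estimated correlation) ended without sham replicate 2 (0.0731), sham replicate 4 (0.12), 14-day replicate 2 (0.115) or 14-day replicate 3 (0.0886). Of 15 astrocyte markers 5 rose, also when adjusted over the list alone, with Gfap at 2.10 ± 0.35 (fry adjusted p = 0.0766).

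At 14 days 1811 genes changed against sham, 927 up and 884 down (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 22 of 34 lists by fry, of which 4 passed with an estimated correlation. The count was 2793 without sham replicate 4, 763, 867 and 701 without 14-day replicate 1, 2 and 3, 2822 with no filter on low counts and 925 when the fit held those 6 libraries alone. With limma on RPKM the split was 1217 up to 542 down with a pseudocount of 1 and 1148 to 480 with 0.1, where the median over all genes was shifted by 0.13 on the log2 scale.

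**Figure D4:**
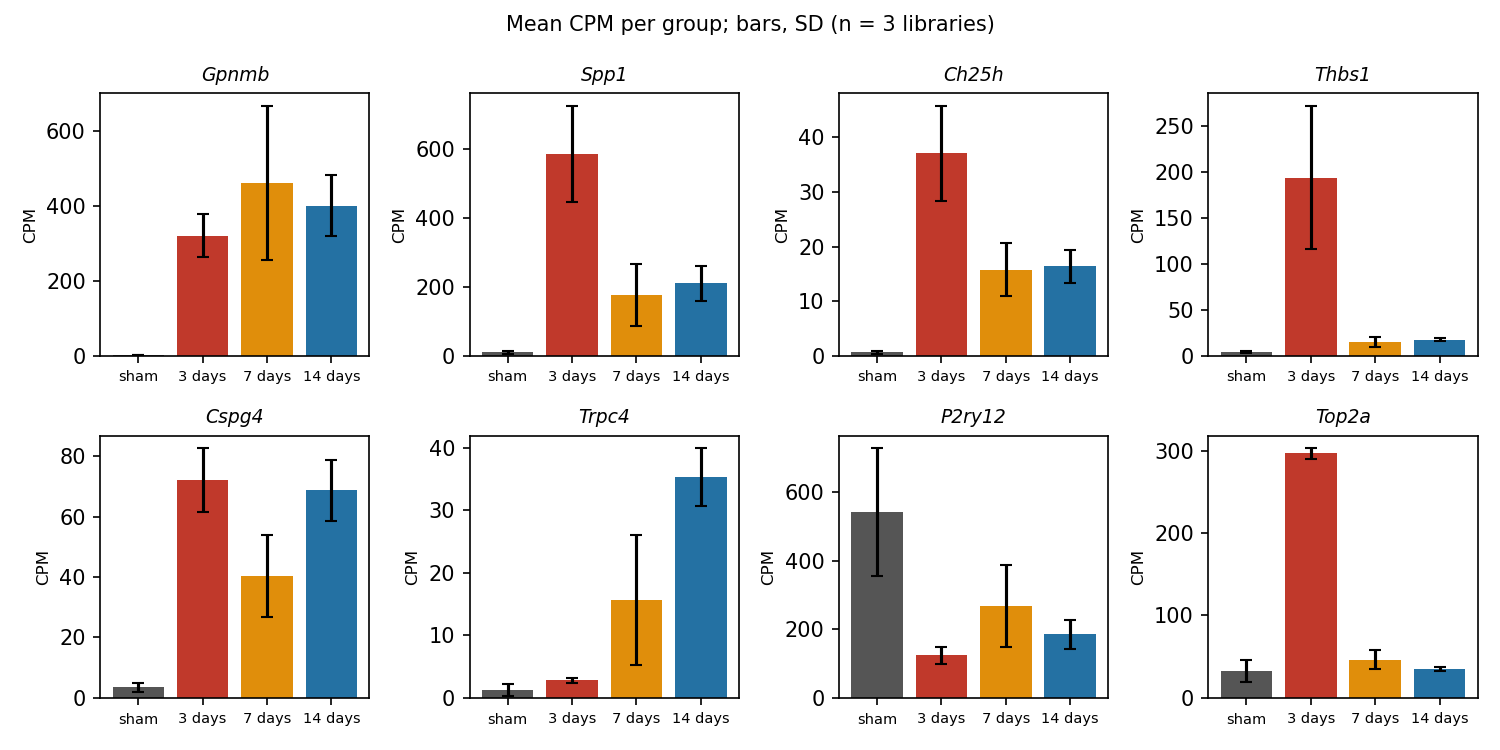
Mean CPM with SD bars (n = 3 libraries) of 8 named genes in sham and at 3, 7 and 14 days, each on its own linear y axis from 0. Top2a is at 296.8 ± 6.4 CPM at 3 days and 46.5 ± 11.6 at 7 days, while Gpnmb is at 320.2, 460.6 and 400.1 CPM at the 3 times.

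From 3 to 7 days all 24 mitosis genes, 13 of 24 DNA replication genes, 12 of 23 interferon-stimulated genes and all 14 endothelial markers fell. With an estimated correlation these 4 lists had adjusted p = 0.112, 0.112, 0.184 and 0.23. For mitosis all 24 genes were lower (fry adjusted p = 0.000309, and adjusted p = 0.112 with an estimated correlation; median log2 fold change -2.26). Examples were Cenpe (-2.62 ± 0.19, edgeR adjusted p = 8.28e-06), the topoisomerase gene Top2a (-2.67 ± 0.27) and the checkpoint kinase gene Bub1 (-2.81 ± 0.31). Of 24 DNA replication genes 13 fell (18 when adjusted over the list alone; fry adjusted p = 0.000309, and adjusted p = 0.112 with an estimated correlation), with Prim1 at -1.76 ± 0.25. Of 23 interferon-stimulated genes 12 fell (17 when adjusted over the list alone; fry adjusted p = 0.00139, and adjusted p = 0.184 with an estimated correlation). Examples were Rsad2 (-1.88 ± 0.31), Stat2 (-1.35 ± 0.23) and Oas2 (-1.38 ± 0.24). Of 24 matrix genes 10 fell and 1 rose (11 and 2 when adjusted over the list alone; fry adjusted p = 0.00483, and adjusted p = 0.32 with an estimated correlation). Examples were Thbs1 (-3.69 ± 0.35), the basement membrane collagen genes Col4a1 (-4.15 ± 0.50) and Col4a2 (-2.94 ± 0.34), and Adam8 (-2.05 ± 0.33). Hmox1 (-3.33 ± 0.32), Arg1 (-2.74 ± 0.40), Cd74 (-2.18 ± 0.31) and Spp1 (-1.73 ± 0.35) fell as well, while Lpl rose by 1.27 ± 0.26. Of 24 homeostatic genes 10 rose and 0 fell (11 when adjusted over the list alone; fry adjusted p = 0.0471, and adjusted p = 0.491 with an estimated correlation). That call ended without 3-day replicate 1, 2 or 3 (fry adjusted p = 0.075, 0.0719 and 0.135), 7-day replicate 1 or 3 (0.105 and 0.0821) or 14-day replicate 1 or 3 (0.0584 and 0.0505), with median-ratio size factors (0.0534) and with a stricter filter on low counts (0.0508).

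All 14 endothelial markers fell from 3 to 7 days (the same when adjusted over the list alone; fry adjusted p = 0.00174, and adjusted p = 0.23 with an estimated correlation), with Kdr at -2.01 ± 0.24, and the vascular genes Tek, Fgd5, Adgrl4 and Slco1a4 were among the largest falls (-4.20 ± 0.74 to -4.74 ± 0.95). Of 16 monocyte-derived macrophage markers 6 fell (10 when adjusted over the list alone), with Ahnak at -2.12 ± 0.33; that call (fry adjusted p = 0.0174, and adjusted p = 0.323 with an estimated correlation) ended without 3-day replicate 2 (0.0644). Of 11 plexins and neuropilins 4 fell (6, with 1 higher, when adjusted over the list alone; fry adjusted p = 0.0128, and adjusted p = 0.323 with an estimated correlation). Of 20 semaphorins 7 fell (8 when adjusted over the list alone; fry adjusted p = 0.0157, and adjusted p = 0.323 with an estimated correlation), with Sema7a at -2.03 ± 0.37 and Sema6b at -1.68 ± 0.35. Both calls ended without 7-day replicate 3 (fry adjusted p = 0.0541 for each), and that for semaphorins with Y-linked expression as a covariate (0.054). Between 3 and 7 days 2466 genes changed, 1079 up and 1387 down (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 10 of 34 lists by fry. By contrast 0 lists passed with camera and an estimated correlation, where 5 had an unadjusted p under 0.05. The count of genes was 4539 without sham replicate 4, 1500, 1465 and 564 without 3-day replicate 1, 2 and 3, 954 and 1088 without 7-day replicate 1 and 3, and 1207 with Y-linked expression as a covariate. The count of lists was 6 without 7-day replicate 3.

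From 7 to 14 days 12 of 14 endothelial, 4 of 14 fibroblast and pericyte and 5 of 15 astrocyte markers rose, and for each list the adjusted p = 0.297 with an estimated correlation. Of 14 endothelial markers 12 rose (14 when adjusted over the list alone; fry adjusted p = 0.0177). Of 14 fibroblast and pericyte markers 4 rose (11 when adjusted over the list alone; fry adjusted p = 0.0203), and of 15 astrocyte markers 5 rose (10 when adjusted over the list alone; fry adjusted p = 0.0203). Tek, the angiopoietin receptor, rose by 4.14 ± 0.74 (edgeR adjusted p = 0.0161), from 1.08 ± 1.31 to 21.6 ± 1.48 CPM, and Slco1a4, a transporter of brain vessels, by 4.27 ± 0.81. Of 19 antigen presentation genes 1 rose and 0 fell (1 and 4 when adjusted over the list alone) while the list moved down (fry adjusted p = 0.0203, and adjusted p = 0.341 with an estimated correlation). Of 23 interferon-stimulated genes 2 fell (10, with 1 higher, when adjusted over the list alone; fry adjusted p = 0.0398, and adjusted p = 0.341 with an estimated correlation). Stab1 fell by 1.22 (edgeR adjusted p = 0.00362), a call that ended without 14-day replicate 1 (0.0607). The damage-associated and mitosis lists did not differ detectably (fry adjusted p = 0.258 and 0.569).

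The calls from 7 to 14 days changed when single libraries were left out. In all 404 genes changed, 250 up and 154 down (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The count was 6 and 7 without 7-day replicate 1 and 3, 1, 34 and 33 without 14-day replicate 1, 2 and 3, 231 and 254 without 3-day replicate 1 and 2, and 1167 and 1774 without sham replicate 2 and 4. The sham and 3-day libraries are not part of this comparison. They act on it only through the spread, filter and scaling that the 12 libraries share in the fit. The count was 1079 with DESeq2, 1562 with no filter on low counts and 1827 when the fit held the 6 libraries alone. With limma on RPKM the split was 228 up to 66 down with a pseudocount of 1 and 171 to 47 with 0.1. The list calls for endothelial, fibroblast and astrocyte markers ended without 14-day replicate 1 (fry adjusted p = 0.0602) or 14-day replicate 2 (0.061), and those for fibroblasts and astrocytes also without 7-day replicate 1 (0.0588) or 14-day replicate 3 (0.0591). The calls for interferon-stimulated genes and antigen presentation ended without 7-day replicate 4 (0.0802 and 0.0721), 14-day replicate 1 (0.112 and 0.0602), 14-day replicate 2 (0.149 and 0.061) or 14-day replicate 3 (0.0939 and 0.0762). That for antigen presentation also ended with a stricter filter on low counts (0.0614). That for interferon-stimulated genes also ended without sham replicate 2 (0.0634), sham replicate 3 (0.0754), 3-day replicate 1 (0.0654) or 7-day replicate 1 (0.0939). The 5 lists called by fry were 2 without 7-day replicate 1, 0 without 14-day replicate 1 or 2 (12 and 8 lists with an unadjusted p under 0.05), 2 without 14-day replicate 3 and 12 without sham replicate 4. With camera and an estimated correlation 0 lists passed, and 4 had an unadjusted p under 0.05.

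From 3 to 14 days cell division and interferon genes were lower, while Lpl, Itgax and some other damage-associated genes were higher. All 24 mitosis genes fell (fry adjusted p = 7.93e-05, median -2.67). Examples were Cenpe (-2.87 ± 0.19, edgeR adjusted p = 2.88e-06) and Mki67, a marker of cycling cells, which went from 1034 ± 108 to 129.2 ± 16.6 CPM (-3.00 ± 0.34). Of 24 DNA replication genes 17 fell (21 when adjusted over the list alone; fry adjusted p = 7.93e-05), with Uhrf1 at -2.32 ± 0.33. Of 23 interferon-stimulated genes 16 fell (20 when adjusted over the list alone; fry adjusted p = 7.93e-05). Examples were Oas2 (-2.27 ± 0.25), Rsad2 (-2.57 ± 0.33) and Stat2 (-1.97 ± 0.23). Slfn4 (-5.33 ± 0.62), Hmox1 (-3.69 ± 0.33), Thbs1 (-3.45 ± 0.35), Ccl2, a chemokine for monocytes (-2.86 ± 0.39), and Stab1 (-1.60 ± 0.15) fell. Of 24 matrix and wound genes, Thbs1 among them, 6 fell, 1 rose and 17 did not pass (7 and 4 when adjusted over the list alone; fry adjusted p = 0.062). Trpc4 (3.66 ± 0.47), the matrix gene Postn (3.42 ± 0.33), St8sia6 (2.00 ± 0.29), the prostaglandin D synthase gene Ptgds (1.98 ± 0.22), Lpl (1.94 ± 0.27) and Itgax (1.63 ± 0.24) rose, and Il6 rose by 2.43 ± 0.45 from its low level at 3 days. Of 24 damage-associated genes 6 rose and 2 fell (10 and 2 when adjusted over the list alone; fry adjusted p = 0.0285, and adjusted p = 0.415 with an estimated correlation). That call ended without 3-day replicate 1, 2 or 3 (fry adjusted p = 0.0875, 0.0562 and 0.0994) or 14-day replicate 2 or 3 (0.093 and 0.0603). The endothelial list did not differ detectably (1 of 14 lower, 3 when adjusted over the list alone; fry adjusted p = 0.543), with the sum at 473.8 ± 249 and 514.1 ± 2.57 CPM.

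Between 3 and 14 days 1349 genes changed, 401 up and 948 down (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 9 of 34 lists by fry, of which 3 passed with an estimated correlation. The count of genes was 2627 without sham replicate 4, 844, 753 and 435 without 3-day replicate 1, 2 and 3, 450, 479 and 470 without 14-day replicate 1, 2 and 3, 2045 with no filter on low counts and 4886 when the fit held those 6 libraries alone. The count of lists was 4 without 3-day replicate 1, 3-day replicate 2 or 14-day replicate 1. With limma on RPKM the split was 556 up to 663 down with a pseudocount of 1 and 474 to 533 with 0.1.

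Across the 3 comparisons with sham, 393 genes were higher and 162 lower at 3, 7 and 14 days alike, and 0 of the genes called at all 3 times differed in direction. The 3-day and 7-day comparisons shared 575 higher and 296 lower genes, where independent lists would share 92.4 and 79.0. For 3 and 14 days these were 653 and 376 against 101 and 81.1, and for 7 and 14 days 488 and 333 against 42.8 and 41.3. In 10 simulations of unchanged groups against the real sham libraries the shared calls averaged 0. The unchanged groups were drawn around the means of those same sham libraries, which leaves out chance deviations of the sham group. The simulations therefore do not measure what shared sham libraries add, with or without effects in both comparisons. The 3 sham libraries are too few to divide, so part of the excess may come from their being shared.

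**Figure D5:**
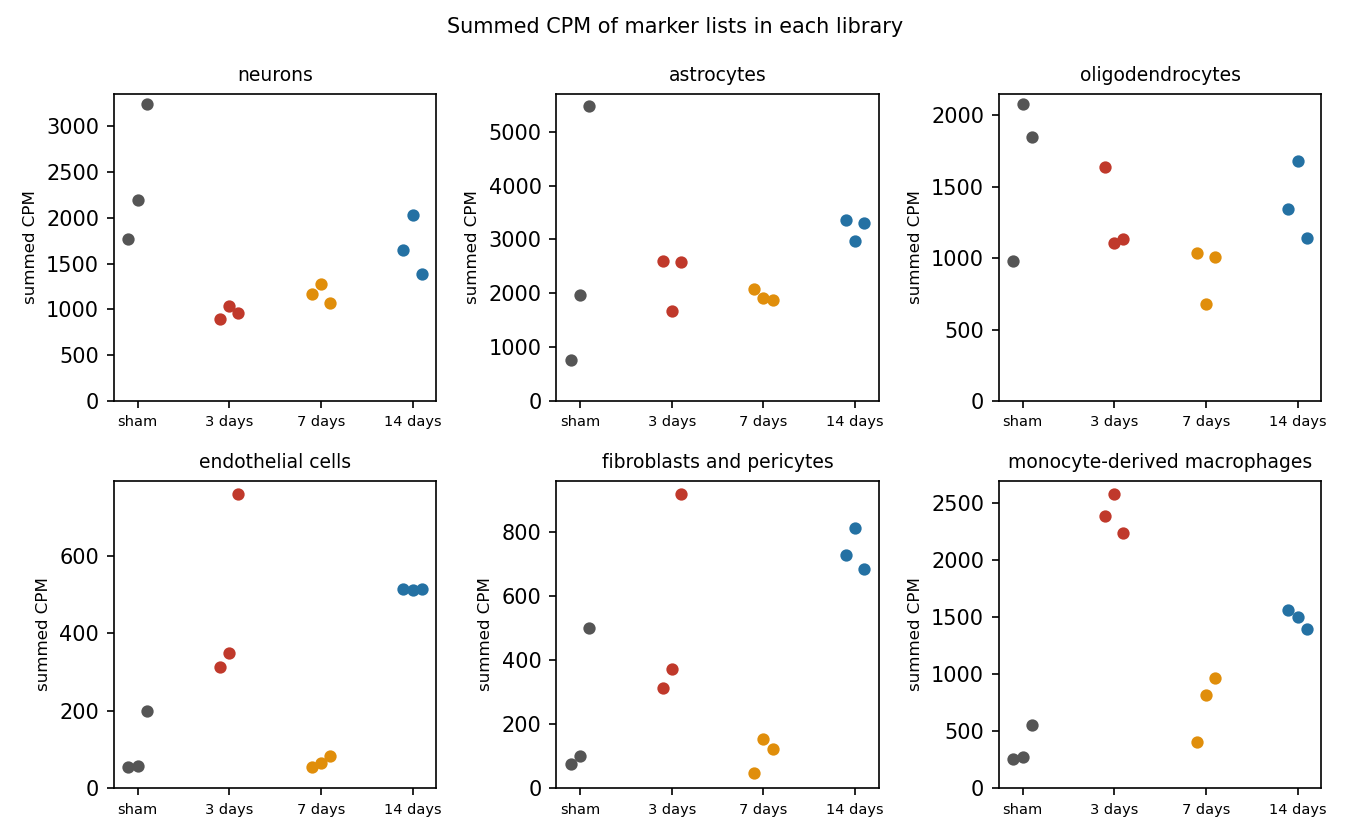
Summed CPM (y axis, linear from 0) of marker lists of 6 other cell types in each of the 12 libraries (points), by group on the x axis. Endothelial markers sum to 473.8 ± 249 CPM at 3 days and 514.1 ± 2.57 at 14 days, against 103.5 ± 83.2 in sham and 67.2 ± 13.9 at 7 days.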

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

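The tests of sex as the source of the marker and Plxnb2 changes, of sequencing depth and of other splits of the libraries were chosen before their results were seen; those of a lower microglial share, of RNA of other cell types (endothelial cells and fibroblasts included) and of monocyte-derived macrophages were chosen after. The test of a lower share replaced a first one, which permuted genes and went against that share but ignored that genes of a list move together. Effects of injury differed between times in direct tests of 1 time against another. Between 3 and 7 days 2466 genes and 10 lists differed, between 7 and 14 days 404 genes and 5 lists, and between 3 and 14 days 1349 genes and 9 lists (edgeR and fry). With camera and an estimated correlation 0, 0 and 3 lists passed (5, 4 and 5 lists at an unadjusted p under 0.05). Plxnb2 differed between 3 and 14 days by -0.69 on the log2 scale. The count from 7 to 14 days was 1 without 14-day replicate 1, 34 and 33 without 14-day replicates 2 and 3, 6 and 7 without 7-day replicates 1 and 3, 231 and 254 without 3-day replicates 1 and 2, and 1167 and 1774 without sham replicates 2 and 4. No test for single outlying libraries was run within the groups of 3.

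Genes called in opposite directions at 2 times numbered 3 for 3 and 7 days and 6 for 3 and 14 days. Kit, Pecam1 and Col4a2 were above sham at 3 days (0.98, 1.02 and 1.78) and below it at 7 days (-1.10, -1.63 and -1.16). Summed endothelial markers were 473.8 ± 249 CPM at 3 days and 67.2 ± 13.9 at 7 days, against 103.5 ± 83.2 in sham. By library they were 54.28, 65.55 and 81.85 CPM at 7 days, and 54.92, 56.02 and 199.6 in sham replicates 2, 3 and 4. Only sham replicate 4 lay above all 7-day libraries, so the sum does not show a fall below sham. Whether these calls arise in microglia was not tested. Cfp, Celsr3, Cenpf, Cdc7, Cit and Stab1 were above sham at 3 days (0.84, 1.27, 1.44, 1.23, 1.30 and 0.65) and below it at 14 days (-1.30, -1.99, -1.22, -1.39, -0.80 and -0.95). The highest edgeR adjusted p of the direct tests between these times was 0.00188, for Kit; the 9 genes were picked for their opposite calls in the same libraries, so these tests add no independent evidence.

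Splits of the 6 libraries of a comparison into 3 and 3 are too few for a share under 0.05, since there are 10. For 3, 7 and 14 days against sham the real counts were 3695, 1712 and 1811, and the highest of the other splits 0, 12 and 0. Between times the real counts were 2466, 404 and 1349, and the highest others 0, 1 and 0. In each of these 6 comparisons 1 split, the real one, gave as many genes. For any difference among the 4 groups 1 of 60 drawn splits, the real one, gave 4872 genes and the highest other 671. That argues against chance for that count. It does not tell injury from other differences between the groups.

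From 7 to 14 days 12 of 14 endothelial, 4 of 14 fibroblast and pericyte and 5 of 15 astrocyte markers rose, but each list had adjusted p = 0.297 with an estimated correlation and its call ended without 14-day replicate 1 (fry adjusted p = 0.0602) or 2 (0.061). Sex of the pools is argued against by a median of 118% of its former value with Y-linked expression as a covariate (2.39 against 2.03 over 43 markers). A lower share of microglial nuclei at 14 days would raise the markers of every other cell type alike, and it stays open: the mean log2 fold change was 2.15 over these lists and 0.42 over the 51 markers of the 5 other lists, with a fry p of the difference of 0.00177, but of 0.0989 once multiplied by the 56 ways to choose 3 of 8 lists. Over the 33 and 29 markers under 20 CPM these values were 0.00212 and 0.119, and the sums went from 67.2 to 514.1 CPM for endothelial cells and from 1174 to 1688 for neurons, whose higher level at 7 days would hide a small added share. A change in vascular cells and astrocytes, or in how much of their RNA came along with the nuclei, may remain as well, and neither was tested.

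Sham replicate 4 lay apart on component 2. Shallower sequencing is argued against, since the gap was 55.3% of the range before and 55% after all libraries were thinned to 1 depth. RNA of other cell types may contribute: in 7 of 8 marker lists the highest sum of the 3 sham libraries was in replicate 4, oligodendrocytes being the exception (1846 CPM against 976.7 and 2083). The ribosomal protein sum of sham replicate 4 lay 2.64 SD below the lowest of the 11 other libraries. Its homeostatic microglia sum was 10570 CPM, against 10550 and 11700 in the other sham libraries. How much ribosomal protein RNA the nuclei of other cell types hold was not measured. These values therefore cannot decide whether RNA of other cell types is the whole cause. No biological explanation was tested, since the design gives none for a single sham library.

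Plxnb2 was higher at 3 days than in sham. Sex of the pools is argued against, since 95.6% of the change was left with Y-linked expression as a covariate (0.58 ± 0.17, edgeR adjusted p = 0.0347). RNA of endothelial cells and fibroblasts stays open. At 14 days their markers were as high, and the upper 95% limit of the Plxnb2 log2 fold change was 0.266. A lower Plxnb2 level within microglia at 14 days would hide such RNA, so these values cannot decide. In 3-day replicate 3 endothelial markers summed to 760.2 CPM, against 311.9 and 349.3 in replicates 1 and 2. Plxnb2 was at 463.9 CPM there, against 459.9 and 479.5. Sham replicate 4 had the highest endothelial and fibroblast sums of sham but the lowest Plxnb2 (259.5 CPM against 318 and 343.1). Both observations go against such RNA, but each rests on 1 library. Monocyte-derived macrophages may contribute and cannot be told apart from a change within microglia: their summed markers were 6.68 times sham at 3 days and 4.13 times at 14 days, no value here fixes how much Plxnb2 they carry, and GFP capture would keep them if they carry the label. Regulation within microglia stays open as well.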

How the results depend on the processing

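The fit with Y-linked expression as a covariate was chosen after the data were seen, and the other alternatives before. With only the 2 groups compared in the fit, the counts of genes were 1817 (3 days), 172 (7 days) and 925 (14 days) against sham, 1827 from 7 to 14 days and 4886 from 3 to 14 days; fewer libraries then set the spread. With no filter on low counts they were 2889 (7 days), 2822 (14 days), 1562 (7 to 14 days) and 2045 (3 to 14 days), with more genes tested. On RPKM the 7-day count was 1137 with a pseudocount of 1 and 1069 with 0.1, and the count from 7 to 14 days 218 with 0.1. DESeq2 gave 1079 from 7 to 14 days. The Y-linked covariate gave 1207 genes from 3 to 7 days and 10 lists from 7 to 14 days. For each of these changes on RPKM, with DESeq2 and with the covariate the cause was not tested.

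The replicate numbers do not pair libraries: over 13 same-numbered pairs the correlations ran from -0.298 to 0.0693 and 2 libraries correlated best with their own number. With the number as a term the fit gave 1608 genes from 7 to 14 days, 16 lists from 3 to 7 days and 11 from 7 to 14 days, and Plxnb2 at 3 days was 0.59 (edgeR adjusted p = 0.0607) while the call for Syn1 at 3 days ended (edgeR adjusted p = 0.0638); the cause was not tested. That fit also ended the list calls for border-associated macrophages at 14 days (fry adjusted p = 0.127) and for interferon-stimulated genes from 7 to 14 days (0.0565). With the 2 groups alone Plxnb2 at 3 days was 0.58 (edgeR adjusted p = 0.0646). Plxnb2 at 14 days turned to 0.05235 and 0.054 on RPKM, and the cause was not tested. With camera and an estimated correlation 10, 6 and 4 lists passed against sham at 3, 7 and 14 days, and 0, 0 and 3 from 3 to 7, 7 to 14 and 3 to 14 days (5 and 4 lists with an unadjusted p under 0.05 for the 2 counts of 0). Camera compares a list with the other genes, a different question from that of fry. The cause of the lower counts was not tested.

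Leaving out 1 library at a time gave 1866 to 4152 genes at 3 days, 827 to 3065 at 7 days, 701 to 2793 at 14 days, 564 to 4539 from 3 to 7 days, 1 to 1774 from 7 to 14 days, 435 to 2627 from 3 to 14 days and 2926 to 6701 for any difference. Lists numbered 6 to 15 from 3 to 7 days, 0 to 12 from 7 to 14 days (0 by fry without 14-day replicate 1 or 2, with 12 and 8 lists at an unadjusted p under 0.05) and 4 to 11 from 3 to 14 days. Plxnb2 ran from 0.4718 to 0.6682 at 3 days and from -0.205 to 0.008588 at 14 days. The cause was not tested.

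Of 10422 alternative values of the 550 named-gene results, 9228 kept their side of the threshold, 1194 lost it with the same direction and 0 reversed. These values leave out Plxnb2 against sham, whose 14-day change did turn positive under some alternatives. List members given only as values and the fits on RPKM are left out too. The most lost calls, 123 of 550, came without 3-day replicate 3. In simulated data with 3 libraries per group and 200 of 18451 genes changed, 14% of 2-fold changes were recovered. How far the share of changed genes, depth, the number of libraries or their spread sets this was not tested.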

Other observations

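Gm26917 and Rn18s-rs5 were singled out after their values were seen, and their CPM are not scaled by TMM. Gm26917, at GRCm38 chromosome 17, 39843013 to 39846341, was higher at 3 days than in sham (log2 fold change 3.79 ± 0.75, edgeR adjusted p = 0.00297, 3 of 3 libraries above the sham libraries). It was also higher at 14 days (2.36 ± 0.70, edgeR adjusted p = 0.0456), with 2653 to 4684 CPM against 208.1 to 1598 in sham. At 7 days it was at 1446, 270.8 and 3295 CPM, overlapping sham (1.30 ± 0.68, edgeR adjusted p = 0.239). The ribosomal RNA gene Rn18s-rs5 was at 151.7 to 240.8 CPM at 3 days, 69.5 to 165.2 at 7 days and 130.5 to 277.5 at 14 days, against 3.50 to 66.5 in sham. No explanation was tested.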
